A study of Mus musculus with 2 samples.

How the data were processed

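H3K27ac ChIP-seq libraries of facial prominence tissue at embryonic day 13.5 were deposited for 2 samples of 1 group, which the labels number as biological replicates 1 and 2. Each sample came from embryos of both sexes pooled, and the labels give each its own tissue record but the same donor record. How independent the replicates are is not given in the sources used here. The p-values and intervals do not measure the spread between single embryos. The labels give mm10 as the genome build.

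The analysis started from peak lists that the authors deposited in narrowPeak format, 1 for each replicate, 1 for the pooled replicates and 1 of replicated peaks. Per the deposited file notes, each replicate's list was made from its own filtered alignments and its own control, the pooled list from the alignments and controls of both, and the replicated list from the pooled list and the lists of both replicates. The peak caller, the aligner, their versions and the overlap rule behind the replicated list are not given in the sources used here. The fold value of each peak is the deposited ratio of ChIP to control signal, and the 2 significance columns hold the deposited −log10 of its p-value and q-value. The smallest −log10 p-value in the deposited lists was 2.00, so peaks were called at a permissive threshold: 7.04% of replicate 1 peaks, 9.69% of replicate 2 peaks, 2.81% of pooled peaks and 0.122% of replicated peaks had a q-value above 0.05. The lists hold no read counts, so the depth of each sample is unknown, and a difference in depth between replicates would change the number of weak peaks. Fold values were used to describe, rank and filter peaks within a list, to match genes on the fold of their replicated promoter region, and in an alternative that applied the same minimum of 4 to both replicate lists. Peaks within a list did not overlap, and the narrowest was 180 bp.

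Gene positions came from the GENCODE release M21 annotation and sequence from the GRCm38 assembly, the assembly on which mm10 is based. No peak extended past a chromosome end (0% in every list). The 8 peaks of replicate 1, 6 of replicate 2, 7 pooled and 7 replicated ones on scaffolds outside the assembled chromosomes are in the counts of overlap and location, but in no shifted set and no gene, domain or motif test. Coordinates are 1-based. A promoter region was a peak within 1 kb of a TSS of any annotated transcript, so it can lie inside a gene, away from the gene's start. A region near TSSs of neighbouring genes counts for each, so a gene can be marked by a region at a neighbour's promoter. A gene with more TSSs has more chances to be marked, and no test matched lists on that number. Other regions were placed in exons, introns or between genes by their summit. Random placement was measured with 100 circular shifts within each chromosome, past the first 3 Mb. Lists of genes (17) and motifs (12), the main tests and most alternatives were fixed before the data were examined. The alternative with regions overlapped by both replicates, the lists of Hippo, retinoic acid, imprinted and T-box genes, and the tests of weak Hox peaks, of lists of other tissues against CpG content, of signal strength and of GC content at the homeodomain motif were chosen after. The lists covered facial mesenchyme transcription factors, Dlx genes, facial epithelium, cartilage and bone, signalling, orofacial clefting, housekeeping, Hox genes, and markers of skeletal muscle, heart, liver, forebrain, peripheral neurons and glia, endothelium, blood, melanocytes and germline. The background was 21938 protein-coding genes on 21 chromosomes, 27 of which share a symbol with another gene.

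Shares of genes with a promoter region were compared by Fisher's exact test, two-sided, list against all other protein-coding genes. Median region width and the median number of distal regions (summit within 50 kb of a TSS, region over 1 kb from any TSS) were compared with 10000 random lists of the same size, two-sided, for which the smallest possible p is 0.00020. Lists with fewer than 3 marked genes were not tested for width. The adjustment was Benjamini-Hochberg within each family, and genes and regions are not independent replicates. CpG content was the largest observed-to-expected CpG ratio within 500 bp of any TSS of a gene, and matched lists took as many genes from each of 10 strata. Motif control windows overlapped no pooled peak, and GC-matched controls were drawn in bins of 2% from windows shifted by 5 to 50 kb. Odds ratios have 95% Wald intervals, and shares have exact Clopper-Pearson intervals.

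Genes were named by a rule set beforehand: per list, up to 4 marked members with the widest promoter region and, for lists mostly unmarked, up to 4 unmarked members in list order; the 25 genes with the widest region over a TSS; the genes in the 20 domains with most covered bases; the 5 replicated regions with the highest fold; and per replicate the 5 strongest peaks that the other did not overlap. Other list members named as examples, in short remainders of a list or as called in 1 replicate were chosen after their values were seen. Alternatives covered the overlap, the fold and p thresholds, the TSS and motif windows, the distance of distal regions, the stitching, the control windows, the pooled list and each replicate alone. No column of per-sample values was left unmapped.

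The tests were checked on simulated data, the gene tests with 22000 genes. All 800 of 2000 simulated regions with a planted overlap were found. Of 200 simulated lists of 36 genes at a share of 92%, 200 had p under 0.05, of 200 lists of 20 genes at 30% 122 did, and of 200 lists of 24 genes at the background share 10 did. Of 30 lists of 30 genes with widths multiplied by 3, 30 passed, and 1 of 30 with unchanged widths did. Of 30 lists with 4 distal regions added per gene 30 passed, and 0 of 30 with none added. All 12 motifs were called when planted in 20% of simulated windows. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, pysam 0.24.0, samtools 1.23.1 and matplotlib 3.10.9.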

Results

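H3K27ac, the acetylation of lysine 27 on histone H3 that marks active promoters and enhancers, was mapped by ChIP-seq in facial prominences of B6NCrl mouse embryos at embryonic day 13.5. The facial prominences are the swellings of cranial neural crest-derived mesenchyme, covered by epithelium, from which the jaws, palate and nose form. The series held 1 group with 2 samples, labelled as biological replicates of tissue pooled from male and female embryos, so the comparisons open to it were between the replicates and between sets of genes or regions within the tissue. The replicate 1 list held 137254 peaks over 63.3 Mb of the genome (build mm10), with a median width of 276 bp. The replicate 2 list held 107541 peaks over 49.2 Mb, with a median width of 280 bp. A list from the pooled reads of both replicates held 128583 peaks over 70.0 Mb, and a list of replicated peaks held 63095 over 53.5 Mb. The depth of sequencing is unknown, since the lists carry no read counts. The binomial intervals below cover counting error only, and fold enrichment over the control is the authors' value for each peak, ranked only within its own list.

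The first comparison asked how far the replicates called the same regions. Of the replicate 1 peaks, 62051 (45.2%, 95% exact binomial interval 44.9 to 45.5) overlapped a replicate 2 peak by at least 1 bp, against 3.66% ± 0.149 (SD, 100 circular shifts) for randomly placed peaks. Of the replicate 2 peaks, 66348 (61.7%, interval 61.4 to 62.0) overlapped a replicate 1 peak, against 4.67% ± 0.185 for shifted ones. Overlapped peaks of replicate 1 had a median fold enrichment of 4.44 and a median width of 462 bp, and the others 3.09 and 223 bp. In replicate 2 the corresponding values were 3.93 and 385 bp, and 3.09 and 213 bp. In the decile of replicate 1 peaks with the highest fold enrichment (7.11 and above), 99.6% were overlapped by replicate 2, and in the lowest decile 22.8%. The corresponding shares of replicate 2 were 99.98% and 38.9%. With 1 library on each side, no test of the difference between the replicates could be made. When only peaks with a fold enrichment of at least 4 in both lists were compared, the shares were 52.4% and 80.6%. Without that minimum on the other list, 77.2% of such replicate 1 peaks and 92.7% of such replicate 2 peaks were overlapped.

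**Figure D1:**
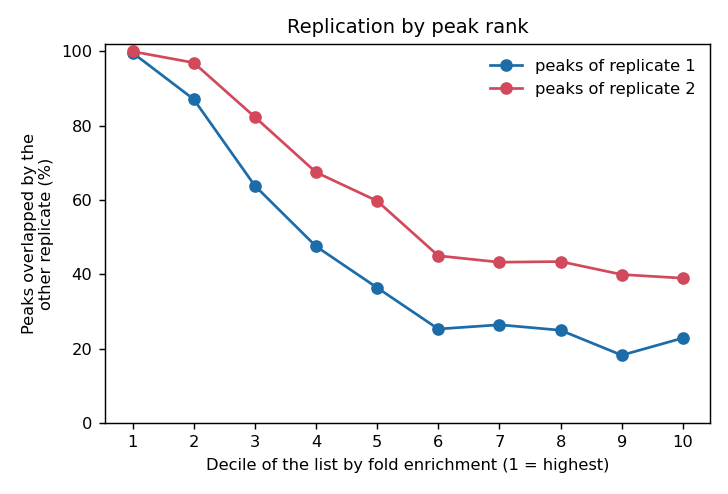
Share of peaks overlapped by the other replicate (y axis, %) per decile of each list ranked by the authors' fold enrichment (x axis, 1 is the highest). Replicate 1 (blue) goes from 99.6% in the highest decile to 22.8% in the lowest, and replicate 2 (red) from 99.98% to 38.9%.

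Among the peaks that only 1 replicate called, the strongest lay at promoters, in introns and between genes. In replicate 1 the highest was the shared promoter of Sass6 and Trmt13 (chromosome 3, 116594955 to 116595577, fold enrichment 9.27), followed by an intronic peak of Sorl1 (chromosome 9, 42053076 to 42053416, 8.58), the promoter of Mdm2, which encodes the ubiquitin ligase of p53 (8.34), and intronic peaks whose nearest promoters were those of B3gnt2 and Cachd1 (both 8.34). In replicate 2 the highest were an intronic peak near Afap1 (chromosome 5, 35980307 to 35980668, 7.26), the promoter of Dhrs7b (7.02), an intronic peak near Tmem140 (6.74) and intergenic peaks 43877 bp from the Gorab and 19355 bp from the Mrgprd promoter (both 6.74). Each of these 10 peaks overlapped a peak of the pooled list.

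The replicated list was a subset of the pooled list: all 63095 rows were identical to pooled rows, 49.1% of them. Replicated regions were stronger and wider than the 65488 regions left out, with a median fold enrichment of 4.27 against 2.76 and a median width of 578 against 224 bp, and 30.6% of them lay at a transcription start site (TSS) against 14.0%. Of the replicated regions, 54520 (86.4%) were overlapped by peaks of both replicates, 5923 by replicate 1 alone, 2528 by replicate 2 alone and 124 by neither. Of the regions left out, 1079 were overlapped by both. Of the pooled peaks with a fold enrichment of at least 4, 98.7% were in the replicated list. All further results rest on this list.

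Replicated H3K27ac regions were concentrated at promoters. In all, 19289 of 63095 regions (30.6%, exact binomial interval 30.2 to 30.9) came within 1 kb of an annotated TSS, 3.59 times the 8.52% ± 0.251 (SD, 100 shifts) of shifted regions. They were also the strongest and widest class, with a median fold enrichment of 6.21, a median width of 807 bp and 41.0% of all covered bases. Any base within 1 kb of a TSS placed a region in this class, so wide regions entered it more readily. How far that rule raised its width was not tested. Intronic regions numbered 25217 (40.0%, against 38.9% ± 0.810 for shifted regions), regions between genes 16223 (25.7% against 49.5% ± 0.973) and exonic regions 2366 (3.75% against 3.07% ± 0.106). The promoter share was 41.1% among regions with a fold enrichment of at least 4 and 22.2% in the pooled list. Of 21938 protein-coding genes, 11908 (54.3%) had a replicated region within 1 kb of a TSS. The separate replicate lists gave the same call for 92.4% of genes, with 1195 genes called in replicate 1 alone and 462 in replicate 2 alone.

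Most genes of the facial mesenchyme, epithelium and cleft lists had H3K27ac at 1 or more of their TSSs. Of 36 transcription factor genes of facial mesenchyme, 33 (91.7%) had a replicated promoter region, against 54.2% of other protein-coding genes (Fisher's exact test, two-sided, Benjamini-Hochberg over the 17 lists, adjusted p = 1.07e-05). They included Prrx1, Msx1, Alx4, Twist1, Tfap2a, Pax3, Lhx8 and Satb2, and those without a region were Tbx22, Hand1 and Tcf21. All 6 Dlx genes, homeobox genes that set dorsoventral identity in the jaw, had a region (adjusted exact p = 0.0454). That call was lost on the pooled list (adjusted exact p = 0.106) and without replicate 1 (0.0563) or replicate 2 (0.106), with all 6 genes still marked. Epithelial genes were marked at the same share, 22 of 24 (91.7%, adjusted exact p = 4.03e-04), among them Trp63 and Irf6, regulators of surface epithelium, the keratin genes Krt5 and Krt14, and Grhl2. At a fold enrichment of at least 4 the epithelial share was 79.2%, and with a TSS window of 500 bp it was 83.3%. Mesenchymal genes stayed at 91.7% in both, and epithelial genes stayed above other genes (adjusted exact p = 0.00672 and 0.00526). The epithelial genes without a region were Wnt9b and St14. Of 35 genes of the BMP, FGF, Hedgehog, WNT, TGF-beta, endothelin, PDGF and Notch pathways, 29 (82.9%) were marked (adjusted exact p = 0.00130), and the 6 without a region included Shh, Fgf8 and Edn1, which encode secreted ligands. Shh and Fgf8 had no promoter peak in any list. Edn1 had one in replicate 2 and the pooled list, Wnt5b and Tcf7 in replicate 1 and the pooled list, and Grem1 in replicate 1. Of 34 genes tied to orofacial clefting, 22 of which also stand in another list, 31 (91.2%) were marked (adjusted exact p = 2.48e-05), all but Tbx22, Vax1 and Wnt9b. Cartilage and bone genes were at 17 of 23 (73.9%, adjusted exact p = 0.0706), with Sox9, Col2a1, Runx2 and Sp7 marked and Acan, Matn1, Comp, Ibsp, Spp1 and Bglap not. All 24 housekeeping genes were marked (adjusted exact p = 5.32e-06). Of the genes named here, Tfap2a, Satb2, Trp63, Irf6 and Runx2 had their widest promoter region inside the gene, over 1 kb from its start. The Trp63 region (chromosome 16, 25802840 to 25803601, fold enrichment 3.45) lay far from that gene's start at 25683763. Other marked genes of these lists can be of this kind too.

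Hox genes stood at the opposite end. None of the 39 Hox genes, which give regional identity to the trunk, limbs and posterior head, had a replicated promoter region, which leaves an exact binomial upper bound of 9.03% (adjusted exact p = 9.06e-13, Fisher's exact test). That bound holds for the replicated list alone, and it and the p-values take the genes as independent although Hox genes lie in clusters. Replicate 2 alone marked 3 of the 39 (upper bound 20.9%), replicate 1 alone 4 (24.2%) and the pooled list 5 (27.4%), each still below other genes (adjusted exact p of 6.17e-08 or less). The 5 were Hoxd3 and Hoxd4, with a peak in both replicates and the pooled list, Hoxa10 and Hoxd8, with one in replicate 1 and the pooled list, and Hoxc13, with one in replicate 2 and the pooled list. Of 18 cardiac genes, 2 (11.1%, adjusted exact p = 5.58e-04) had a region, at Myh7 and Irx4, and Nkx2-5, Gata4, Gata5 and Tbx20 had none. The cardiac genes Tbx5, Myh6 and Hcn4 had a peak in replicate 1 but not in replicate 2, and Tbx5 and Hcn4 also had one in the pooled list. Of 22 forebrain genes, 4 (18.2%, adjusted exact p = 0.00179) had a region: Bcl11b, Emx2, Sox2 and Lhx2. The Lhx2 region (chromosome 2, 38350490 to 38350814) lay at an annotated TSS inside the gene, which starts at 38339281. Foxg1, Emx1, Pax6 and Neurod1 had no replicated region, although Foxg1 had a peak in replicate 1 and in the pooled list. Pluripotency and germline genes were at 3 of 16 (18.8%, adjusted exact p = 0.00759), with Klf4, Dazl and Pou5f1 marked and Nanog, Zfp42, Dppa3 and Dppa4 not. The Pou5f1 region (chromosome 17, 35509593 to 35509863, fold enrichment 3.10) also lay at an internal TSS, and that gene starts at 35506018.

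Genes of liver, blood, skeletal muscle and pigment cells were also marked less often than other genes. Liver genes were at 5 of 22 (22.7%, adjusted exact p = 0.00720, Fisher's exact test), with Apoh, Cebpa, Prox1, Trf and Apoa2 marked and Alb, Afp, Apoa1 and Apob, the genes of major plasma proteins, not. Blood and immune genes were at 5 of 22 as well (22.7%, adjusted exact p = 0.00720), with Runx1, Klf1, Tal1, Cd68 and Slc4a1 marked. The globin genes Hba-a1, Hbb-bs and Hbb-bt had no region, which is uncertain because each has a near-identical copy. Skeletal muscle genes were at 6 of 20 (30%, adjusted exact p = 0.0498): Tnnt3, Pax7, Tnnt1, Tnni1, Myog and Chrna1 were marked, and the muscle determination genes Myod1, Myf5 and Myf6 were not. The Tnnt3 region (chromosome 7, 142513597 to 142517829) lay over the end of the gene, which runs from 142498836 to 142516009, and not at its start. Of 8 melanocyte genes only Pmel was marked (12.5%, adjusted exact p = 0.0390), and Dct had a peak in both replicates but no region in the pooled list. Whether the Pmel and Apoh regions belong to those genes or to a neighbour's promoter was not tested. The muscle call was lost without replicate 1 (adjusted exact p = 0.0901) and without replicate 2 (0.202), and the melanocyte call likewise (0.346 and 0.0942). Endothelial genes (10 of 17, adjusted exact p = 0.810) and genes of peripheral neurons and glia (7 of 17, adjusted exact p = 0.354) did not differ detectably from other genes. The endothelial genes Tie1, Sox17, Emcn and Robo4 had a peak in replicate 1 but not in replicate 2, and no endothelial gene the reverse. Sox17, Emcn and Robo4 also had one in the pooled list.

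The lists differed in the CpG content of their promoters, with a median observed-to-expected ratio of 0.627 over all genes, 0.722 for Hox genes, 0.790 for forebrain genes and 0.259 for blood genes. Against random lists matched on promoter CpG content, the Hox, cardiac, forebrain and germline lists were still lower (matched means 74.8%, 41.7%, 74.2% and 57.2%) and the mesenchymal, epithelial, cleft and housekeeping lists higher (76.3%, 60.9%, 75.0% and 80.3%), with adjusted permutation p from 0.00170 to 0.0355. Cartilage and bone genes were above their matched lists, which had 48.5% (adjusted permutation p = 0.00680). For skeletal muscle, liver, blood, melanocyte, endothelial, neuron and glia, Dlx and signalling genes the difference from matched lists was not detectable, with adjusted permutation p of 0.748, 0.496, 0.988, 0.151, 0.366, 0.100, 0.684 and 0.988.

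**Figure D2:**
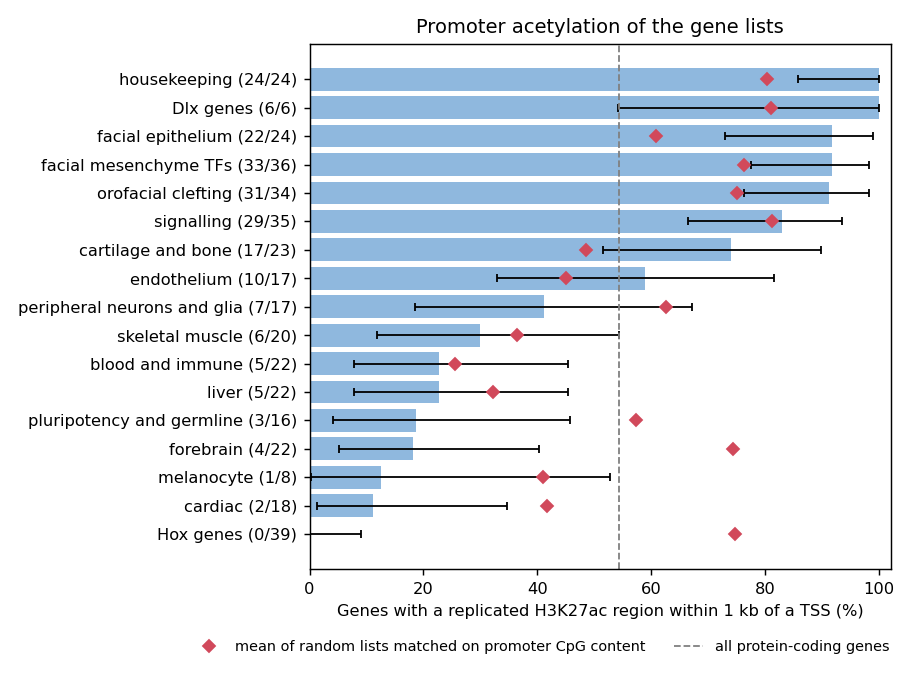
Share of the genes of each list with a replicated H3K27ac region within 1 kb of a TSS (bars, x axis in %), with exact binomial 95% intervals (black lines), the mean share of random lists matched on promoter CpG content (red diamonds) and the share of all protein-coding genes (54.3%, dashed line). Housekeeping, Dlx, epithelial, mesenchymal and cleft lists reach 91.2% or more, and no Hox gene is marked.

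Promoter regions were wide at mesenchymal, signalling, cleft, and cartilage and bone genes. At the 33 marked mesenchymal transcription factor genes the widest region at a TSS had a median width of 4023 bp, against 1184 bp in random lists of marked genes (adjusted permutation p = 9.33e-04, two-sided, 10000 lists). The widest region was taken over every annotated TSS of a gene, and random lists were not matched on the number of TSSs. Signalling genes had a median of 3535 bp and cleft genes of 2660 bp (both adjusted permutation p = 9.33e-04), and cartilage and bone genes of 2596 bp (adjusted permutation p = 0.00140). The size of these differences in bp changed with the processing and with replicate 1 left out. The mesenchymal difference from random lists, 2839 bp, was 5474 bp when regions within 500 bp were joined and 1904 bp without replicate 1. Without replicate 1 the signalling difference went from 2350 to 1546.5 bp, the cleft difference from 1472 to 1045 bp, and the cartilage and bone difference from 1411 to 637 bp (adjusted permutation p = 0.0306). Random lists were narrower there too. For the mesenchymal list the random median fell from 1184 to 807 bp and its own median from 4023 to 2711 bp. For cartilage and bone these went from 1185 to 813 bp and from 2596 to 1450 bp. The raw p of the mesenchymal, signalling and cleft lists was 0.00020, the smallest that 10000 random lists can give. Epithelial genes did not differ detectably from random lists, with a median of 1262 bp (adjusted permutation p = 0.778), and lay below random lists by a difference of -228 bp without replicate 1 and -99.0 bp without replicate 2. The difference of 2761 bp between the epithelial and mesenchymal medians passed a permutation test (p = 0.00021, 100000 resamples). Peripheral neuron and glia genes had narrower regions, with a median of 518 bp over 7 genes (adjusted permutation p = 0.0454), a call lost without replicate 2 (adjusted permutation p = 0.0809). Endothelial regions had a median of 637 bp (adjusted permutation p = 0.0677), and passed the threshold on the pooled list (0.00480) and without replicate 2 (0.0139). Medians of the Dlx (1307 bp), skeletal muscle (1402 bp), forebrain (2506 bp), liver (630 bp), blood (681 bp), germline (748 bp) and housekeeping (1560 bp) lists did not differ detectably from random lists (adjusted permutation p from 0.0740 to 0.778), except that blood genes passed without replicate 1 (0.0117). When regions within 500 bp were joined, the Dlx, forebrain, endothelial and housekeeping lists passed the threshold and the neuron and glia list did not.

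**Figure D3:**
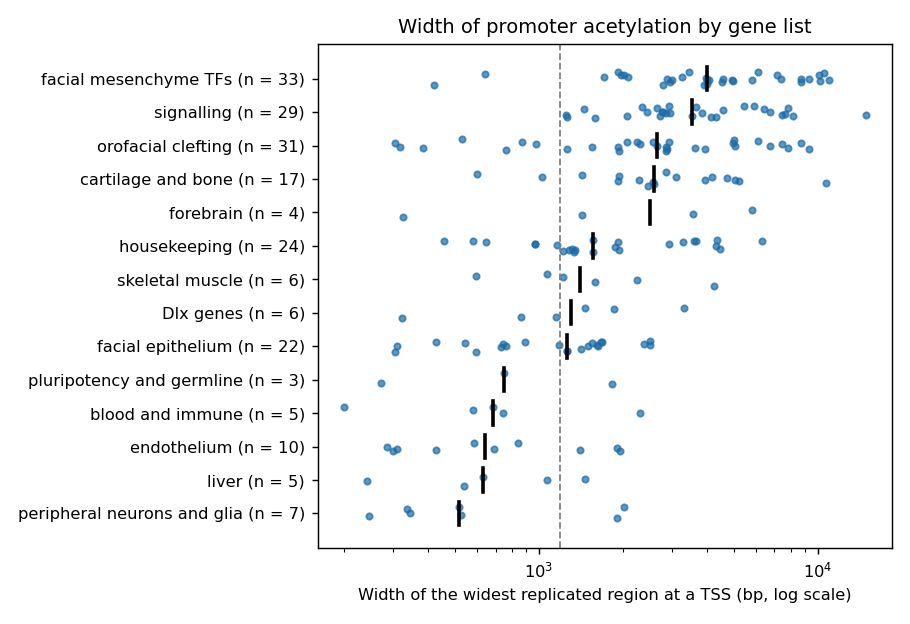
Width in bp (x axis, log scale) of the widest replicated region at a TSS for each marked gene (points) by list, for lists with at least 3 marked genes. Black bars are medians, and the dashed line is the median of all marked genes (1184.5 bp), with the mesenchymal median at 4023 bp and the neuron and glia median at 518 bp.

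The widest single region over a TSS lay at Tbx2, a T-box repressor gene (chromosome 11, 85828559 to 85845541, 16983 bp). It was followed by Tnrc18 (16332 bp), Wnt5a, a WNT ligand gene needed for facial outgrowth (chromosome 14, 28503859 to 28518825, 14967 bp), Smad7, an inhibitor of TGF-beta signalling (14691 bp), Trio (14607 bp), Id3 (11337 bp) and Zmynd8 (11243 bp). Mesenchymal and skeletal genes followed with Prrx1 (chromosome 1, 163304849 to 163315845, 10997 bp), Col1a1, which encodes a chain of type I collagen (10738 bp), Lhx8 (10544 bp), Alx4 (10178 bp) and Pax3 (10109 bp). The retinoic acid receptor genes Rara (10569 bp) and Rarg (10461 bp), the T-box gene Tbx3 (10456 bp), the WNT receptor gene Fzd2 (10044 bp), Wwp2 (10693 bp), Gnai2 (10463 bp), Cic (10070 bp), Tns2 (9994 bp), Prdm16 (9796 bp), Bcl9l (9602 bp) and Zfp532 (9490 bp) were also among the 25 widest. The Col1a1 (fold enrichment 5.31), Rara and Rarg regions lay inside their genes, over an annotated TSS away from the gene's start. The regions at Tbx2, Tbx3, Wnt5a, Prrx1, Lhx8, Alx4 and Pax3 covered the gene's start. For the other genes of the 25 this position is not given here, and some of their regions may also lie inside the gene. Ldb1 and Pprc1 shared a region of 10422 bp. Replicate 1 peaks covered 90.3% or more of each of these regions. Replicate 2 peaks covered 84.9% or more, except at Col1a1, where they covered 65.1%.

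Distal H3K27ac regions were more numerous near mesenchymal, signalling, cleft, Dlx, and cartilage and bone genes. Mesenchymal transcription factor genes had a median of 7 distal regions within 50 kb of a TSS, against 1 in random lists (adjusted permutation p = 0.00113). Alx4 had 34, Prrx2 30, Pax3 21 and Prrx1 19. Signalling and cleft genes had a median of 6 each (both adjusted permutation p = 0.00113), with 40 at Fgfr2, which encodes an FGF receptor, and 24 at Axin2, a target gene of WNT signalling. Regions were counted around every annotated TSS of a gene, and Fgfr2 is annotated from 130162451 to 133123350 on chromosome 7. Its count may thus include regions far from its marked promoter. No alternative matched lists on the number or spread of TSSs. Dlx genes had a median of 8 (adjusted permutation p = 0.0245), a count shared among neighbours since these genes lie in pairs, and cartilage and bone genes of 4 (adjusted permutation p = 0.0245). The cartilage and bone call was lost when only regions overlapped by both replicates were kept, an alternative chosen after seeing the data (adjusted permutation p = 0.0618). Epithelial genes had a median of 3 (adjusted permutation p = 0.134), and passed the threshold without replicate 1 (0.0248) and without replicate 2 (0.0108). Hox genes had a median of 0 (adjusted permutation p = 0.703), and were below random lists without replicate 1 (0.0248), without replicate 2 (0.00340) and on the pooled list (0.0197). Medians of the other lists lay between 0 and 2.5 and did not differ detectably from random lists (adjusted permutation p from 0.243 to 1).

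Regions within 10 kb of each other were stitched into 25969 domains, and the 20 with most covered bases held 2.49% of all covered bases. The first (chromosome 1, 161968891 to 162257545, 93 regions covering 136065 bp) spanned promoters of Dnm3 and Pigc and the noncoding genes Dnm3os, Mir199a-2 and Mir214. Dnm3os is the precursor transcript of the microRNAs. The second (chromosome 6, 50908459 to 51174832, 105 regions covering 115907 bp) held no annotated TSS, and its nearest protein-coding gene was Nfe2l3. The third (chromosome 7, 142453875 to 142612286, 87148 bp covered) held Lsp1, Tnnt3 and Mrpl23 with the imprinted noncoding gene H19. Others in the 20 lay at Abr and Nxn, near Zfp36l1, at Cstad, at the microRNA genes Mir23b, Mir27b and Mir24-1, at the imprinted gene Mest, at Ahdc1 and Wasf2, at Sept9, at Nfix and Cacna1a, at Prrx2, at the WNT effector gene Tcf7l1, at Vgll4 and Atg7, at Ski and Morn1, at Zmynd8, at Ptma, at Ddc and Fignl1, and at Bcl11b. The Alx4 domain (chromosome 2, 93586511 to 93697313) held 40 regions covering 54658 bp, of which replicate 1 peaks covered 52048 bp and replicate 2 peaks 43545 bp. Of the 20 domains, 13 stayed among the first 20 with stitching within 5 kb, 13 within 20 kb, 13 without replicate 2 and 11 when ranked by width times fold enrichment.

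**Figure D4:**
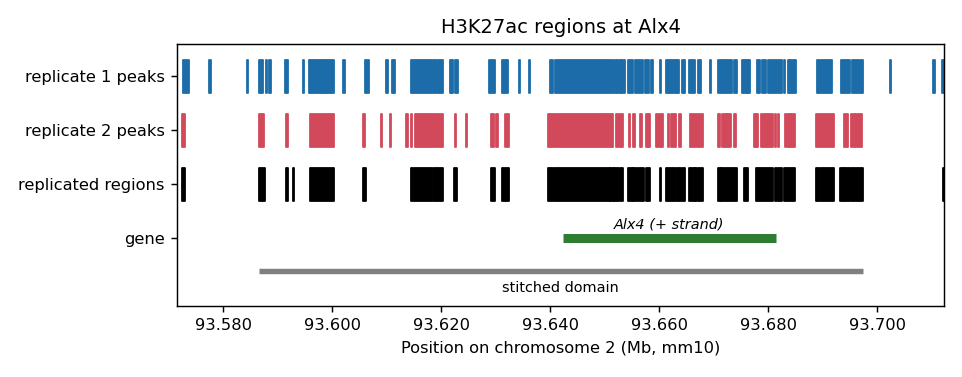
Map of the Alx4 locus on chromosome 2 (x axis, position in Mb, mm10) with the peaks of replicate 1 (blue) and replicate 2 (red), the replicated regions (black), the gene (green) and the stitched domain from 93586511 to 93697313 (grey). The 40 regions of the domain lie on both sides of the gene and within it.

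By fold enrichment, the strongest replicated regions were promoters. The highest was that of Tnrc18 (chromosome 5, 142810136 to 142826467, fold enrichment 71.7). The next (chromosome 5, 115488640 to 115490384, 68.5) held only TSSs of the noncoding genes Gm24265 and Gm24407, with the Sirt4 promoter 5396 bp away. The others were the promoters of Brd2, which encodes a reader of acetylated histones (chromosome 17, 34117946 to 34124181, 66.7), the histone methyltransferase gene Kmt5b (chromosome 19, 3766858 to 3769385, 65.5) and Alx4 (chromosome 2, 93640721 to 93650898, 64.8).

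Sequence motifs were compared between 43795 distal regions, within 500 bp of the summit, and 38918 windows shifted by 5 kb that held no pooled peak. AP2 sites were present in 26.3% of regions and 17.6% of control windows (odds ratio 1.67, 95% interval 1.62 to 1.73), CTCF sites in 1.24% and 0.691% (1.80, 1.55 to 2.08), TEAD sites in 49.2% and 43.0% (1.28, 1.25 to 1.32) and forkhead sites in 15.4% and 13.1% (1.21, 1.16 to 1.26). The E-box bound by TWIST-type factors was present in 62.4% and 58.1% (1.20, 1.16 to 1.23), and an E-box within 10 bp of a homeodomain site in 1.30% and 0.994% (1.31, 1.15 to 1.49). MEF2 sites had an odds ratio of 1.30 (1.18 to 1.43). GATA sites were rarer in the regions (10.6% against 13.1%, 0.782, 0.749 to 0.816), as were SOX sites (0.925, 0.889 to 0.963), and HNF4 sites did not differ detectably (1.02, 0.909 to 1.15). Of 12 motifs, 11 passed Fisher's exact test with Benjamini-Hochberg adjustment, the scrambled E-box with the largest adjusted p of these (odds ratio 1.09, adjusted p = 0.00959). The homeodomain core was rarer than in the shifted windows (22.7% against 24.6%, odds ratio 0.897, 0.869 to 0.927), but with control windows matched on GC content it was more frequent (1.23, 1.19 to 1.27). GC content was 47.2% in regions and 44.8% in shifted windows, and windows are not independent replicates. With windows of 250 bp the calls of the combined site (odds ratio 1.12), SOX (0.950) and MEF2 (1.16) were lost. With matched controls AP2 had an odds ratio of 1.30, CTCF of 1.39, MEF2 of 1.61, the combined site of 1.48 and the scrambled E-box of 1.04 (adjusted exact p = 0.165).

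**Figure D5:**
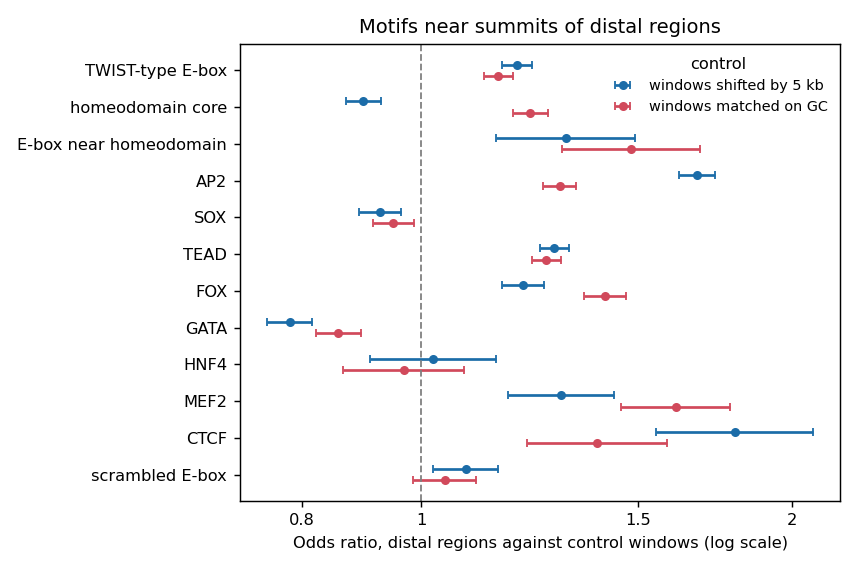
Odds ratio (x axis, log scale) for a motif within 500 bp of the summit of distal regions against windows shifted by 5 kb (blue) and against windows matched on GC content (red), with 95% intervals as lines. AP2 and CTCF lie highest against shifted windows (1.67 and 1.80), GATA lowest (0.782), and the homeodomain core lies on opposite sides of 1 for the 2 controls.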

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

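The tests of single tissue lists, of the 9 lists of other tissues and cell types together, of weak Hox peaks, of signal strength and of the homeodomain motif were chosen only after the results were seen. No result met a rule for a closer look. The series has 1 group, so no biological difference between groups was tested. Gene class and signal strength were weighed from within the tissue, and the share of epithelial cells itself was not measured.

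None of the 39 Hox genes and few genes of most lists of other tissues had a replicated promoter region. Low CpG content could leave promoters unmarked, but the Hox list had a median CpG ratio of 0.722 against 0.627 over all genes. It could thus not explain the Hox list, whatever the matched test gave. Lists matched on CpG content held 29.2 marked genes on average (range 18 to 37 of 39, permutation p = 0.00020, the smallest possible). Weak peaks left out of the replicated list do not account for the missing Hox regions. With a peak of any list counted, 5 of 39 Hox genes were marked against 62.8% of others (Fisher's exact p = 1.60e-10). Hox genes lie in clusters, and both tests took neighbours as independent, so these p-values overstate the evidence. Over all 9 lists of other tissues and cell types together, endothelium and peripheral neurons and glia included, 43 of 162 genes were marked against 74.7 in matched lists (range 54 to 93, permutation p = 0.00020, the smallest possible). Of the 7 lists that were low against all genes, cardiac (permutation p = 0.00160), forebrain (p = 0.00020) and germline genes (p = 0.00140) were each below their matched lists. For skeletal muscle (6 genes against 7.28 matched, permutation p = 0.660), liver (5 against 7.08, p = 0.379) and blood (5 against 5.63, p = 0.963), CpG content alone may account for the low share. For melanocyte genes (1 against 3.28, permutation p = 0.0976) 8 genes were too few to decide.

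Epithelial promoter regions were narrower than those of mesenchymal transcription factors, with medians of 1262 and 4023 bp. The class of gene could matter, but the 8 epithelial transcription factor genes had a median of 1341.5 bp, also narrower (permutation p = 0.0442, close to the threshold). Lists matched on CpG content differed by a median of 129 bp (permutation p = 1e-04, the smallest possible). Weaker signal, as from a smaller share of epithelial cells in the tissue, would go with narrower regions, and median fold enrichment was 5.38 at epithelial and 16.0 at mesenchymal promoters. Lists matched on fold enrichment differed by 896 bp in the same direction, less than the 2761 bp observed (permutation p = 1e-04, the smallest possible), so signal strength may be part of the difference and did not give its whole size. The medians of the matched lists were 697.5 bp for the epithelial and 1599 bp for the mesenchymal list, so by these medians both lists were wider than genes of like signal, the mesenchymal list by more.

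The homeodomain core was rarer in distal regions than in shifted windows (odds ratio 0.897). GC content is a candidate explanation: regions were richer in GC (47.2% against 44.8%), the motif is made of A and T, and with controls matched on GC content the odds ratio was 1.23 (interval 1.19 to 1.27).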

How the results depend on the processing

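The alternative that kept only regions overlapped by peaks of both replicates was chosen after seeing the data; the other alternatives were planned. Of the planned values, 312 kept their direction and side of the threshold, stayed within their interval or, for counts, stayed within 1.5 times the main count, 17 lost the threshold, 15 gained it, 14 reversed and 26 moved; of the added values, 63, 1, 1, 0 and 1 did. Peaks within a list did not overlap, so taking them as listed changed nothing by construction. Where no cause is named, the cause was not tested. Depth is unknown, so how far it limits the weak peaks cannot be given. No paired analysis was possible because the series has 1 group.

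The share of replicate 1 regions overlapped went from 45.2% to 34.8% when 50% of the region had to be covered, to 52.4% at a fold of at least 4 in both lists and to 76.6% for the 20000 lowest p. For replicate 2 these were 52.4%, 80.6% and 82.2%. In the highest decile of replicate 1 the share was 99.7% ranked by p and 97.2% with the larger overlap, and in the lowest 18.5% and 14.9%. In replicate 2 the highest decile had 99.7% with the larger overlap, and the lowest 36.6% and 28.4%. Of pooled peaks with a fold of at least 4, 98.7% were replicated. The promoter share was 27.2% with a window of 500 bp, 36.1% with 2 kb, 26.7% with protein-coding TSSs, 22.2% on the pooled list, 41.1% at a fold of at least 4, 32.7% with regions of both replicates, and 21.8 to 24.7% on single replicates.

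The number of lists past the threshold for promoter marking, 14, was 15 with the 2 kb window, 13 on the pooled list, 12 at a fold of at least 4 and 11 with 1 replicate left out, whichever it was, all within that tolerance. For promoter marking, as the difference from other genes in percentage points, cartilage and bone passed the threshold with the 2 kb window (22.7) and on the pooled list (23.1). On the pooled list the Dlx (40.5) and skeletal muscle (-19.5) calls were lost. At a fold of at least 4 the muscle (-24.6) and melanocyte (-37.1) calls were lost and the endothelial difference reversed (-8.45, adjusted exact p = 0.629). Without one replicate, values were 40.0 to 43.3 for Dlx, -21.7 to -15.0 for muscle and -35.0 to -19.2 for melanocyte genes, each past no threshold.

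For width, 8 lists in place of 5 passed when regions within 500 bp were joined, with differences from random lists of 2172.5 bp for Dlx, 3009 for forebrain, -821 for endothelium and 1027 for housekeeping; the neuron and glia call was lost (-596) and muscle reversed (-77.0). On the pooled list forebrain reversed (-197), neuron and glia lost the call (-585) and endothelium gained it (-665). Without one replicate, values were -228 to -99.0 for epithelium and -348 to -194 for muscle, both reversed, -518 to -515 for neurons and glia (call lost without replicate 2), -526 to -338 for endothelium (call gained without replicate 2) and -549 to -387 for blood (call gained without replicate 1).

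The number of lists past the threshold for width was 5 of 14 tested in the main analysis, and 6, 7 and 6 of 16 on the pooled list, without replicate 1 and without replicate 2. There the Hox list and 1 other list (cardiac or melanocyte) reached 3 marked genes and were tested too. Hox genes passed each time as narrow, with medians of 227, 180 and 196 bp over 5, 3 and 4 genes (adjusted permutation p = 0.00448, 0.0117 and 0.00448), and the other list did not pass (adjusted permutation p = 0.0860, 0.218 and 0.564). Hoxd3 and Hoxd4, counted each time, start at 74711927 and 74711929 on chromosome 2, so 1 peak may count for both. The p-values take the genes as independent. A width of 180 bp is that of the narrowest peak in any list. The number for distal regions, also 5, was 6 with the 100 kb distance, 6 on the pooled list and 7 with 1 replicate left out, whichever it was. For distal regions, as the difference of medians, the 100 kb distance gave 1.5 for blood, reversed, and -2 for Hox genes, which passed; the pooled list gave -3 for Hox genes. With regions of both replicates epithelium passed (2) and cartilage and bone did not (2). Without one replicate, values were 4.5 to 6 for epithelium and -4 to -2 for Hox genes, which passed on either replicate, and -0.5 to 0.5 for blood, reversed without replicate 2.

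Of the 20 domains, 13 were kept with stitching within 5 kb, 13 within 20 kb and 11 ranked by width times fold. For motifs, a window of 250 bp lost the calls of the combined site (odds ratio 1.12), SOX (0.950) and MEF2 (1.16). HNF4 reversed with windows shifted by 20 kb (0.909), matched on GC (0.967) and on single replicates (0.934 to 0.990), homeodomain reversed with GC matching (1.23), a control that removes the GC difference, and the scrambled E-box lost its call there (1.04).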

Other observations

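The lists in this part and all their tests were chosen after the widest regions and the 20 domains had been seen, where members of each list stood out. Tests on the whole lists would count those members, so the values below leave out genes with 1 of the 25 widest regions and genes within 50 kb of 1 of the 20 domains: Vgll4 of the Hippo list, Rara and Rarg of the retinoic acid list, Igf2, Mest and Grb10 of the imprinted list, and Tbx2 and Tbx3 of the T-box list. The choice of the lists themselves still rests on those regions. Their shares of marked genes are compared below with all other protein-coding genes, not with lists matched on promoter CpG content. For the earlier lists such matched means ran from 25.6% (blood) to 81.1% (signalling). How far CpG content accounts for the shares below was not tested.

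Genes of the Hippo pathway, which sets tissue growth through YAP, TAZ and TEAD proteins, were marked at 20 of 22 remaining promoters (90.9%, Fisher's exact test, adjusted p = 0.00145 over 4 lists), all but Vgll1 and Vgll2. The marked ones had a median width of 2278.5 bp (adjusted permutation p = 8.00e-04), and all 22 genes a median of 5.5 distal regions (adjusted permutation p = 0.00160), with 38 at Tead1 and 20 each at Amotl1 and Amotl2. Retinoic acid genes were marked at 9 of 16 promoters, which did not differ detectably from other genes (adjusted exact p = 1), but the marked ones were wide, with a median of 2873 bp (adjusted permutation p = 0.00200). All 16 genes, marked or not, had a median of 5 distal regions (adjusted permutation p = 0.00640). Cyp26b1 (8129 bp) and Crabp2 (6505 bp) were the widest of these. At Cyp26b1, Rarb, Rxra and Stra6 the widest region lay inside the gene, at an annotated TSS away from its start. The same held for Amotl1, Amotl2, Lats2 and Stk3 of the Hippo list. In the replicated list synthesis and degradation genes were each split: of the synthesis genes Rdh10 was marked (2873 bp) and Aldh1a1, Aldh1a2 and Aldh1a3 were not, and of the degradation genes Cyp26b1 was marked and Cyp26a1 and Cyp26c1 were not. Of the unmarked ones, Aldh1a3 and Cyp26c1 had a promoter peak in replicate 1 alone and Aldh1a2 in replicate 2 alone.

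Imprinted genes were marked at 16 of 20 promoters (80%, adjusted p = 0.0476, Fisher's exact test, close to the threshold) and had a median of 4 distal regions (adjusted permutation p = 0.0173). Peg10 and Sgce were marked by the same region (chromosome 6, 4745939 to 4747158), which counts for both genes. A test that counts it once was not run, so the call on marking is uncertain. The width of the imprinted genes' regions did not differ detectably from random lists (median 1220 bp, adjusted permutation p = 0.887). At Plagl1, Snrpn, Igf2r, Impact and Gnas the widest region lay inside the gene, at an annotated TSS away from its start. T-box genes did not differ detectably in marking (6 of 15, adjusted exact p = 0.409), width (1289.5 bp, adjusted permutation p = 0.887) or distal regions (median 1, adjusted permutation p = 1).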
